A study of Mus musculus with 16 samples.

How the data were processed

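RNA-seq was done on hippocampus of C57BL/6JNarl mice in 4 groups of 4 libraries, which the labels give by sex and by condition (non-stressed or chronic-stressed). The libraries were made from 1 ug of total RNA extracted with 1-bromo-3-chloropropane, using a VAHTS Universal V8 kit. The submitters' processing notes name HISAT2 2.0.1, HTSeq 0.6.1 and the genome build GRCm39; the strand setting of counting and the annotation release are not stated. The deposited table holds 55359 genes with whole-number counts per gene and library, and the authors also give FPKM, that is counts scaled by exonic length and library total, which was checked by recomputing it from the counts (largest difference 0.00500). Symbols are lacking for 1438 genes. Totals ran from 15.2 to 32.5 M counts (M, 1e+06) per library. Replicate libraries of a group differed by more than counting error (lowest chi-square per degree of freedom 3.11 between replicates), so each was taken as its own library.

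The design fixed before the data were examined planned limma on log2 FPKM. Since the table also held counts, the gene test was changed to edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, TMM scaling, all 16 libraries with 4 group means). The planned test, limma 3.58.1 on FPKM, became an alternative. Genes with FPKM of at least 0.5 in at least 4 of 16 libraries were tested (17569 genes). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The comparisons were females against males within each condition, stressed against non-stressed within each sex, and the interaction, coded as the female minus the male stress effect. Errors after ± are SE for log2 fold changes and SD for CPM and shares, with n = 4 per group. Where a group held no count of a gene, the fold is given as a bound at a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with its exact (Clopper-Pearson) interval; floors and intervals cover counting error only.

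The 41 gene lists, fixed in advance, cover sex-linked genes, stress hormone and steroid genes, immediate early and clock genes, cell types and regions of and around the hippocampus, receptors, synapse, mitochondria, ribosome, immune, chaperone, histone and noncoding genes. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests a list without comparing it to other genes. Named genes followed a rule also fixed in advance: among genes that passed with a mean FPKM of at least 1 and no overlap between groups, the 12 largest changes each way, here a part of them; up to 4 passing members of each list by smallest p; the 3 members with the smallest p of a list that passed camera; the 10 smallest p where fewer than 5 genes passed; and Xist, 4 Y-linked genes, Nr3c1, Nr3c2, Fkbp5, Bdnf and Esr1 always. Genes that are not protein coding were counted and, outside the lists, not named. Of the genes this rule allows, some whose call rests on a single library were left out of the text, and some others are not reported here.

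Opposite-strand neighbours were taken from the coordinates in the deposited table (overlap, or within 5 kb). Biotype, GC content and the share of exonic bases that overlap exons on the opposite strand came from GENCODE M21, matched by Ensembl identifier (98.8% of tested genes), with GenomicRanges 1.54.1 and Biostrings 2.70.1. Alternatives planned before were DESeq2 1.42.0, limma with pseudocounts of 0.1, 0.5 and 1, no or a stricter filter, TPM, median-ratio and quantile scaling, array weights, weights by pool size, fits to the compared groups alone, a robust spread, a replicate block and each library left out in turn. Chosen after seeing the data were fits without TMM, with a length and GC trend removed by splines, on genes with no opposite-strand gene within 5 kb, with both, without non-stressed female libraries 1 and 4, and with all libraries thinned to the lowest total, and the list tests with each library left out in turn. Tested on simulated data, with counts for 17569 genes with 200 changed, edgeR found 71 of 100 changes of 2-fold and 47 of 100 of 1.5-fold in the male stress comparison, with 5 false calls; the numbers were 71, 37 and 4 in the female stress comparison, 71, 45 and 4 between the sexes of non-stressed and 78, 56 and 13 of chronic-stressed mice, and 54, 7 and 5 for the interaction. Shares of counts were compared with 2-sided exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.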

Results

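The study measured RNA in the hippocampus of C57BL/6JNarl mice of both sexes under non-stressed and chronic-stressed conditions, with 4 libraries in each of the 4 groups. The labels give each library a pool size, 3 in 3 of the groups and 1 or 2 in the chronic-stressed males, taken here as animals per library. They do not state whether pools shared animals. Library totals ran from 15.2 to 32.5 M counts (M, 1e+06), with means of 17.2 ± 1.88 M in non-stressed males, 18.1 ± 1.80 M in non-stressed females, 23.2 ± 6.42 M in stressed males and 23.4 ± 4.74 M in stressed females (SD, n = 4). Across 17569 tested genes, the first principal component held 65.6% of the variance and set all 8 stressed libraries apart from all 8 non-stressed ones. The second held 11.3% and set non-stressed female library 4, and less so library 1, apart from the other libraries of their group. The median SD of log2 CPM (counts scaled to the library total, times 1e+06) was 0.16 in non-stressed males, 0.28 in non-stressed females, 0.11 in stressed males and 0.10 in stressed females.

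**Figure D1:**
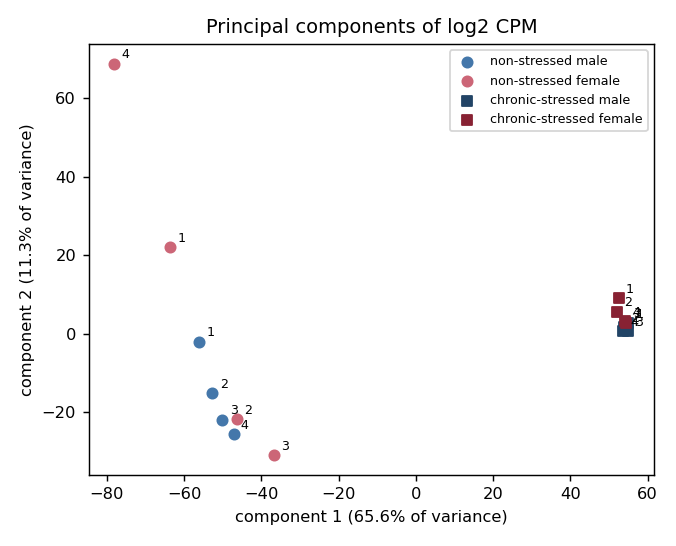
Principal components of log2 CPM over the tested genes, 1 point per library, with the replicate number beside it; circles are non-stressed and squares chronic-stressed libraries. The horizontal axis (65.6% of the variance) parts the conditions and the vertical axis (11.3%) sets non-stressed female library 4 apart.

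The make-up of the libraries also differed between conditions. Genes coding for cytosolic ribosomal proteins took 1.05 ± 0.0509% in non-stressed males, 1.25 ± 0.415% in non-stressed females, 0.616 ± 0.00965% in stressed males and 0.630 ± 0.00746% in stressed females. Mitochondrially encoded genes took 8.47 ± 0.546% in non-stressed males, 7.40 ± 0.723% in non-stressed females, 5.99 ± 0.225% in stressed males and 6.07 ± 0.387% in stressed females. Genes with under 1 kb of exonic length took 3.29 ± 0.246% in non-stressed males, 3.45 ± 0.756% in non-stressed females, 2.01 ± 0.0797% in stressed males and 2.03 ± 0.0756% in stressed females, and genes over 6 kb 36.3 ± 0.858% in non-stressed males, 35.6 ± 3.66% in non-stressed females, 43.8 ± 0.384% in stressed males and 43.7 ± 0.215% in stressed females. In each sex every stressed library lay on the same side of every non-stressed one for each of these shares (2-sided exact permutation p = 0.0286, the smallest that 4 against 4 allow; Benjamini-Hochberg adjusted p = 0.0971 over 68 such tests). The mitochondrial gene mt-Nd6, a complex I subunit and the lone protein-coding gene on the light strand, stood at 1681 ± 251 CPM in non-stressed males, 1720.0 ± 551 CPM in non-stressed females, 98.7 ± 9.81 CPM in stressed males and 84.1 ± 16.4 CPM in stressed females. Its heavy-strand neighbour mt-Nd5 stood at 5686 ± 386 CPM in non-stressed males, 4113 ± 1695 CPM in non-stressed females, 5832 ± 283 CPM in stressed males and 5708 ± 389 CPM in stressed females.

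In the hippocampus of non-stressed mice, the genes that differed between the sexes lay on the X and Y chromosomes. Of 17569 genes tested, 8 passed, 3 higher and 5 lower in females, and 0 of them were autosomal by edgeR. At an unadjusted p under 0.05 there were 1199 genes, DESeq2 called 15 genes and limma 10, and edgeR without non-stressed female libraries 1 and 4 called 16. Xist, the noncoding RNA that silences 1 X chromosome in females (GRCm39 chromosome X, 102503972 to 102526860), stood at 565 ± 64.3 CPM in females against 1.81 ± 1.59 in males (SD, n = 4; log2 fold change 8.25 ± 0.78 (SE), adjusted p = 2.1e-05). The X-linked genes Eif2s3x, a translation initiation factor subunit, and Kdm6a, a histone demethylase, both of which escape inactivation, were higher in females by 0.67 ± 0.09 and 0.50 ± 0.07 on the log2 scale (adjusted p = 0.00306 and 0.00515). Neither passed with the compared groups alone in the fit, nor Kdm6a after rescaling to TPM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were lower in females, with log2 fold changes of -6.05, -6.73, -6.47 and -7.43 (highest adjusted p = 1.5e-07), together with 1 further Y-chromosome gene that is not protein coding. Their counts were not 0 in females: Ddx3y stood at 2.77, 0.162, 0.148 and 1.25 CPM in libraries 1 to 4, against 67.6 ± 6.27 in males. Without library 1 their log2 fold changes became -7.06, -8.37, -7.57 and -8.54 (Uty, on 2 counts), and without non-stressed male library 4 that of Xist 8.90. Xist overlaps Tsix on the opposite strand, and whether counting kept the strands apart is not stated, so its level is uncertain to that extent.

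The genes fixed in advance for stress hormones and growth factors did not pass between the sexes of non-stressed mice. The glucocorticoid receptor Nr3c1 had a log2 fold change of 0.10 ± 0.07 (adjusted p = 0.664) and the mineralocorticoid receptor Nr3c2 -0.11 ± 0.10 (adjusted p = 0.690). For the receptor co-chaperone Fkbp5 it was 0.22 ± 0.10 (adjusted p = 0.651) and for the neurotrophin Bdnf 0.03 ± 0.13 (adjusted p = 0.955). The estrogen receptor gene Esr1 lay below the expression filter and was not tested in any comparison. Among 41 gene lists, 13 passed the camera test at its preset correlation. The Y-linked list (adjusted p = 9.0e-08 with an estimated correlation) and the list of X genes that escape inactivation (adjusted p = 4.7e-05 with an estimated correlation) were those that held with an estimated one. No member of the other 11 passed on its own. Ribosomal protein genes (median log2 fold change 0.26, camera adjusted p = 1.6e-08) and nuclear genes of oxidative phosphorylation (0.24, 6.4e-09) had positive medians, with Rplp2 at 0.51 ± 0.20 and Ndufb10 at 0.38 ± 0.16. Both lists had adjusted p = 0.673 with an estimated correlation, and the direction of both tests turned negative without non-stressed female libraries 1 and 4. Positive medians also came from immediate early genes (camera adjusted p = 0.0217; Nr4a2 at 0.33), endothelial genes (0.0407; Kdr at 0.32), meningeal fibroblast genes (0.0296; Ptgds at 0.63) and blood genes (0.0155; Hbb-bt at 0.92). These had adjusted p = 0.631, 0.631, 0.653 and 0.631 with an estimated correlation. Interferon and antigen presentation genes (camera adjusted p = 2.0e-04; Cd74 at 1.00), heat shock genes (0.0163; Hspb1 at 0.75) and genes of endoplasmic reticulum stress (1.8e-04; Pdia6 at 0.35) had adjusted p = 0.631, 0.544 and 0.544 with an estimated correlation. Negative medians came from mitochondrially encoded genes (camera adjusted p = 2.0e-04; mt-Cytb at -0.27; adjusted p = 0.544 with an estimated correlation) and glutamate receptor genes (0.0296; Grm7, the member with the smallest p, at 0.18; adjusted p = 0.631 with an estimated correlation). With no opposite-strand neighbour the immediate early, endothelial, meningeal, glutamate, heat shock and endoplasmic reticulum lists did not pass, and the mitochondrially encoded list, whose genes all have such a neighbour, could not be tested. Without non-stressed female libraries 1 and 4 those of endothelial, blood, glutamate, interferon, heat shock and endoplasmic reticulum genes did not, nor, with the length and GC trend removed, those of meningeal and glutamate genes. With 1 library left out at a time, a setting for lists chosen after seeing the data, the Y-linked, X escape, interferon and endoplasmic reticulum lists passed in all 16 fits. The ribosomal list was lost without non-stressed female library 4 (adjusted p = 0.658), where its direction turned negative, and that of oxidative phosphorylation without non-stressed female library 4 (adjusted p = 0.837). Mitochondrially encoded genes did not pass without non-stressed female library 3 (adjusted p = 0.116), immediate early genes without non-stressed male library 1 or 2 or non-stressed female library 3 (adjusted p from 0.0643 to 0.984) and endothelial genes without non-stressed male library 1 or 2 or non-stressed female library 2, 3 or 4 (adjusted p from 0.0543 to 0.234). Nor did meningeal genes without non-stressed male library 1 or 4 or non-stressed female library 2 or 3 (adjusted p from 0.144 to 0.583), blood genes without non-stressed male library 1 or non-stressed female library 1 or 4 (adjusted p from 0.0514 to 0.234), heat shock genes without non-stressed male library 1 or non-stressed female library 4 (adjusted p from 0.0525 to 0.149) or glutamate receptor genes without non-stressed male library 4 or non-stressed female library 1 or 4 (adjusted p from 0.0957 to 0.355). Without non-stressed female libraries 1 and 4, Nr3c2 (0.02), Bdnf (-0.15) and Ndufb10 (-0.05) changed sign. Bdnf did so too with array weights (-0.08) and without non-stressed male library 2 or 3 or non-stressed female library 4 (-0.08 to -0.02).

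**Figure D2:**
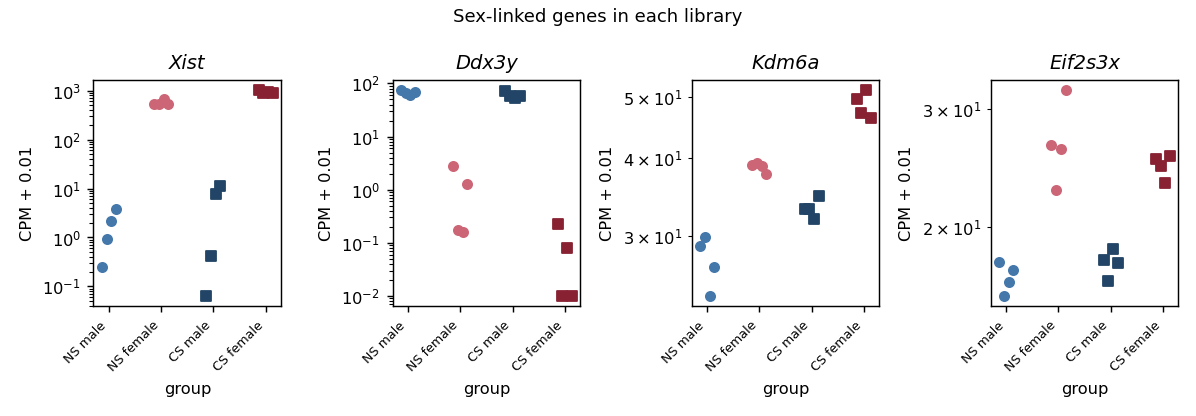
CPM plus 0.01 on a log axis for Xist, Ddx3y, Kdm6a and Eif2s3x in each group (NS, non-stressed; CS, chronic-stressed), 1 point per library. Ddx3y in non-stressed female libraries 1 and 4 stands at 2.77 and 1.25 CPM, above the other female libraries.

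In chronic-stressed mice the sexes differed at the same X- and Y-linked genes. edgeR called 7 genes, 2 higher and 5 lower in females and 0 of them autosomal, and all 7 were among the 8 of the non-stressed mice with the same sign. By the same test 146 genes had an unadjusted p under 0.05. DESeq2 called 11 genes, limma 9, limma with array weights 13, and edgeR on the libraries of these groups alone 11. Xist stood at 937 ± 67.7 CPM in stressed females and 4.96 ± 5.66 in stressed males (log2 fold change 7.49 ± 0.72, adjusted p = 2.5e-05), with 0.0536, 0.413, 7.87 and 11.5 CPM in male libraries 1 to 4. Without male library 4 its log2 fold change became 8.20. Kdm6a was higher in females (0.55 ± 0.07, adjusted p = 0.00128), and Eif2s3x, at 0.48 ± 0.09, did not pass (adjusted p = 0.127). It did pass without non-stressed female library 2 or 4 (0.48 and 0.48). Ddx3y, Eif2s3y, Kdm5d and Uty were lower in females (-9.75, -9.21, -8.49 and -8.20; highest adjusted p = 2.4e-08). Without stressed female library 1, which held most of their few female counts, these became -10.87, -10.87, -9.80 and -9.83. Nr3c1 (0.01 ± 0.07), Nr3c2 (0.00 ± 0.10), Fkbp5 (-0.11 ± 0.10) and Bdnf (0.12 ± 0.13) did not pass (lowest adjusted p = 1). Left-out libraries changed the sign of these small values for Nr3c1 (without stressed male library 3 or 4 or stressed female library 1, -0.02 to 0.00) and Nr3c2 (without stressed male library 2 or 4 or stressed female library 1, 3 or 4, -0.04 to 0.00).

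Of the gene lists, 10 of 41 passed camera in stressed mice at the preset correlation, and 3 held with an estimated one. Those were the Y-linked list (adjusted p = 3.8e-11 with an estimated correlation), the X escape list (adjusted p = 1.6e-07 with an estimated correlation) and immediate early genes, which mark recent neuronal activity and had a positive median in females (median log2 fold change 0.24, adjusted p = 0.0398 with an estimated correlation). Fos, a member of that list, had a log2 fold change of 0.97 ± 0.22 but did not pass on its own (adjusted p = 0.594). Microglia (camera adjusted p = 7.0e-04; C1qa at 0.27) and inflammatory genes (0.0184; Nfkbia at 0.29) had positive medians, with adjusted p = 0.571 and 0.571 with an estimated correlation. Markers of tissue next to the hippocampus or its vessels had negative medians in females: choroid plexus (camera adjusted p = 0.00614; Aqp1 at -0.46), meningeal fibroblasts (0.00620; Islr at -0.35), blood (3.0e-08; Alas2 at -0.98) and thalamus (0.00511; Synpo2 at -0.25). Dentate granule neuron genes did too (0.00851; Dsp at -0.29). These 5 had adjusted p = 0.910, 0.617, 0.155, 0.571 and 0.617 with an estimated correlation, and none of the members named passed alone. With no opposite-strand neighbour the choroid plexus, meningeal, thalamus and inflammatory lists did not pass, and the dentate granule neuron list, with 2 such genes, could not be tested. The inflammatory list did not pass without non-stressed female libraries 1 and 4 either. With 1 library left out at a time, a setting for lists chosen after seeing the data, the Y-linked, X escape, immediate early and blood lists passed in all 16 fits (highest adjusted p for blood = 0.00347). Alas2 moved to -0.39 without stressed male library 2, whose haemoglobin share was 0.0324%. Microglia genes did not pass without stressed female library 3 (adjusted p = 0.485), inflammatory genes without stressed male library 1 or stressed female library 3 (adjusted p from 0.0534 to 0.967) and thalamus genes without stressed male library 2 or stressed female library 2 (adjusted p from 0.0506 to 0.483). Nor did choroid plexus genes without stressed male library 1, 2 or 4 or stressed female library 1 or 2 (adjusted p from 0.0506 to 0.795), meningeal genes without stressed male library 2 or stressed female library 3 or 4 (adjusted p from 0.0768 to 0.713) or dentate granule neuron genes without stressed male library 3 or 4 or stressed female library 2 (adjusted p from 0.0506 to 0.154).

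In males, chronic stress went with changes at 6976 of 17569 genes, 3254 higher and 3722 lower in stressed libraries; 860 changed over 4-fold, 267 up and 593 down. Among the large rises were Pdcd2, a ribosome assembly factor with no count in any non-stressed male library (at least 174-fold higher, at a floor of 3 counts over the group), and the pseudouridine synthase Pus3 (log2 fold change 5.29 ± 0.34, adjusted p = 8.3e-09). The glucosamine phosphate acetyltransferase Gnpnat1 (log2 fold change 4.24 ± 0.23, adjusted p = 8.5e-10), the protocadherin Pcdhga10 (3.29 ± 0.31) and the integrin-linked kinase Ilk (3.11 ± 0.22) also rose. Among the large falls were the cytokine Il4, which had no count in stressed males against 18.2 ± 1.25 CPM in non-stressed ones (at least 559-fold lower), and Proz, a cofactor of a blood clotting inhibitor (1 count against 1068, a ratio of 1428 with a 95% counting interval from 256 to 56442). The kinase Hipk4 (log2 fold change -8.17 ± 0.22, adjusted p = 1.3e-13), Fer1l5 (-7.81 ± 0.42) and Pter (-5.63 ± 0.20) fell as well. The cholesterol transporter Star, which feeds steroid synthesis, had a log2 fold change of -2.20 ± 0.18 (adjusted p = 1.1e-07). Each of these genes lies within 5 kb of a gene on the opposite strand, for example Pdcd2 beside Tbp, Il4 beside Kif3a and Hipk4 beside Pld3. How counting treated strand is not stated, so their changes are uncertain and may come from counting rather than from stress. Of genes changed over 4-fold in both sexes, 79.0% have such a neighbour, against 66.3% of all tested genes, and 65.7% overlap it, against 43.0%. Among the 5927 genes without one, edgeR refitted to them alone called 2110, and 1699 with a trend of length and GC content also removed, where both settings were chosen after seeing the data. Rescaling FPKM to TPM, against limma on FPKM without rescaling, moved the median log2 fold change of all genes by 0.22 in males and 0.23 in females. The share of limma calls that were rises went from 44.3% to 75.3% in males and from 46.5% to 73.8% in females, and lists whose median lies within that shift of 0 have no fixed direction.

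In females, 8668 of 17569 genes changed with chronic stress, 3879 higher and 4789 lower, 865 of them over 4-fold (269 up and 596 down). The large changes were at many of the genes named for males: Pdcd2 (no count in non-stressed females; at least 197-fold higher), Pus3 (log2 fold change 4.87 ± 0.32, adjusted p = 8.6e-09), Gnpnat1 (log2 fold change 4.42 ± 0.23, adjusted p = 5.0e-10), Pcdhga10 (3.64 ± 0.31) and Ilk (3.37 ± 0.22) rose. In turn Hipk4 (log2 fold change -8.43 ± 0.23, adjusted p = 1.3e-13), Fer1l5 (-7.36 ± 0.40), Pter (-5.94 ± 0.20) and Star (-2.68 ± 0.18) fell. Il4 had 1 count over the stressed female libraries against 1339 (ratio 1736, 95% counting interval from 311 to 68629.9) and Proz 2 against 948 (ratio 615, from 169.7 to 5083). The same doubt about strand holds for these genes here. Prl, the pituitary hormone prolactin, fell (-7.90 ± 1.65, adjusted p = 0.00106), and 1 library set most of that value. Non-stressed female libraries 1 to 4 had 2.20, 1.84, 1.53 and 186 CPM, and without library 4 the log2 fold change was -3.19. The hormone precursor gene Pomc went the same way (-2.50, or -1.10 without that library). Leaving out a library also moved Fer1l5 without stressed female library 1 (-8.00), Pus3 without non-stressed female library 2 (5.59) and Prl without stressed female library 4 (-9.32). Without non-stressed female libraries 1 and 4, a setting chosen after seeing the data, edgeR called 5594 genes. Among genes with no opposite-strand neighbour it called 2650, and 2120 with the trend removed.

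**Figure D3:**
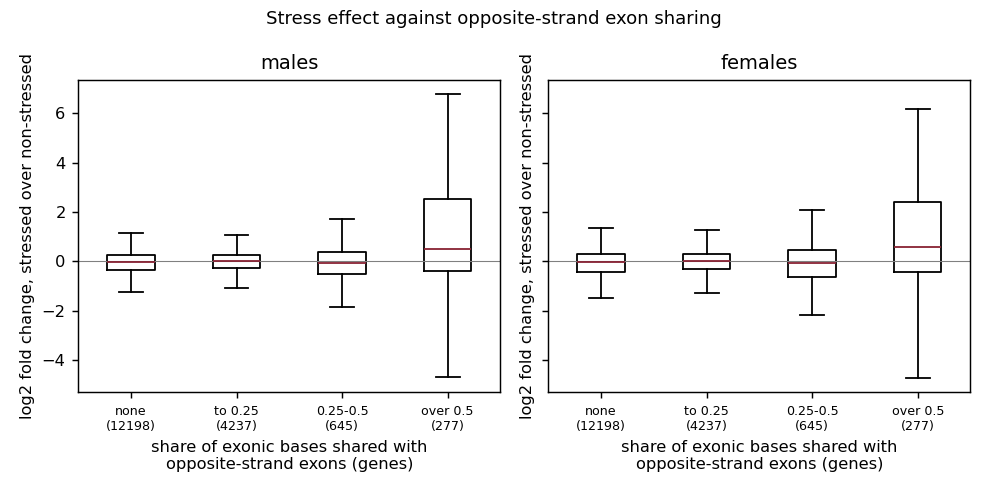
Log2 fold change with stress in males and females by the share of a gene's exonic bases that lies opposite to exons of another gene; boxes span the quartiles around the median, whiskers reach 1.5 box lengths at most and points beyond are not drawn. The median stands at -0.05 and -0.05 for genes sharing none and at 0.50 and 0.58 for genes sharing over 0.5.

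Genes that glucocorticoids induce did not pass as a group in either sex (camera adjusted p = 0.523 in males and 0.742 in females). Members of it and of the corticoid list below changed about as often as all tested genes (39.7% called in males and 49.3% in females). Of 18 measured glucocorticoid-responsive genes, 5 rose, 3 fell and 10 did not pass in males, against 4, 4 and 10 in females. Adjusted over this list alone, 8 and 7 passed. The lipid droplet gene Plin4 rose from 2.56 ± 0.415 to 6.40 ± 0.894 CPM in males (log2 fold change 1.32 ± 0.23, adjusted p = 2.7e-04) and from 2.95 ± 0.840 to 5.89 ± 1.86 in females (1.00 ± 0.22, adjusted p = 0.00171). Fkbp5 rose in males from 42.8 ± 4.70 to 60.3 ± 7.19 CPM (0.50 ± 0.10, adjusted p = 0.00102), while in females 0.16 ± 0.10 did not pass (adjusted p = 0.2004), except without non-stressed female library 3 (0.27). Hif3a rose in males (1.26 ± 0.24, adjusted p = 6.2e-04), and the transcription factor Zbtb16 in females (1.38 ± 0.35, adjusted p = 0.00433, or 1.99 without non-stressed female library 3). Ddit4, which restrains mTOR signalling, fell in both (-0.56 and -0.42), and the cell cycle inhibitor Cdkn1a fell in females (-0.51). Among the 11 corticoid receptor and stress peptide genes, 2 were higher and 3 lower in stressed males and 6 did not pass, with 2, 3 and 6 in females. Calls adjusted over that list alone numbered 5 and 6. The receptor co-chaperone Fkbp4 fell (-0.49 in males and -0.59 in females) and the PACAP receptor Adcyap1r1 rose (0.50 and 0.53), and the PACAP gene Adcyap1 fell in males (-0.54). The list did not pass camera (camera adjusted p = 0.743 in males and 0.999 in females). Nr3c1 was higher in males (0.22 ± 0.07, adjusted p = 0.0216) but missed the threshold without non-stressed male library 2, 3 or 4 or stressed male library 1 or 2 (log2 fold changes from 0.19 to 0.21). In females it stood at 0.13 ± 0.07 (adjusted p = 0.122), passing without non-stressed female library 3 (0.22). With the length and GC trend removed, Nr3c1 was at -0.019 in males and -0.17 in females, Nr3c2 at -0.02 in males and Fkbp5 at -0.20 in females, each a change of sign. Nr3c2 was higher in females (0.25 ± 0.10, adjusted p = 0.0376; not past the threshold without non-stressed female library 1 or 4 or stressed female library 1, 3 or 4, with log2 fold changes from 0.18 to 0.25) and stood at 0.14 ± 0.10 in males (adjusted p = 0.256). Calls here were lost with the length and GC trend removed (Fkbp5 and Ddit4 in males and Ddit4 and Nr3c2 in females), after rescaling to TPM (Ddit4 and Cdkn1a in females), with array weights (Nr3c2 in females), with the compared groups alone (Nr3c2 in females), with thinned counts (Nr3c1 in males) and without non-stressed female libraries 1 and 4 (Cdkn1a and Nr3c2 in females). Of the genes named here, Plin4, Fkbp5, Hif3a, Cdkn1a and Nr3c2 overlap a gene on the opposite strand and share the doubt about strand.

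**Figure D4:**
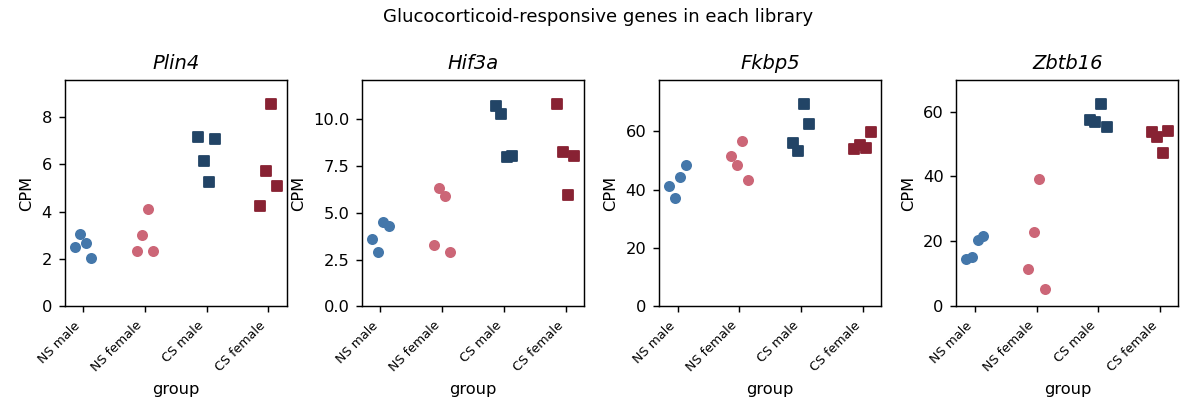
CPM of Plin4, Hif3a, Fkbp5 and Zbtb16 in each group (NS, non-stressed; CS, chronic-stressed), 1 point per library, each axis from 0. Every stressed male library lies above every non-stressed male library for the 4 genes.

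Clock genes rose in both sexes, 9 of 15 in each. The circadian clock list (15 measured) had 9 rises, 0 falls and 6 not passing in males, and 9, 1 and 5 in females. Circadian clock genes gave 11 and 12 calls adjusted over the list alone. The list passed camera (camera adjusted p = 3.1e-05 in males and 0.00254 in females), with adjusted p = 0.235 and 0.773 with an estimated correlation, and did not pass in either sex among genes with no opposite-strand neighbour. Its median was 0.49 in males and 0.41 in females, 0.27 and 0.28 with the length and GC trend removed, and 0.71 and 0.66 under TPM. The clock component Per3 had log2 fold changes of 1.05 ± 0.08 in males and 0.91 ± 0.08 in females (adjusted p = 7.3e-08 and 3.7e-07). The output transcription factor Dbp (0.74 ± 0.08 and 0.58 ± 0.07), Clock (0.58 and 0.48) and Tef (0.49 and 0.41) rose too. Of 20 measured immediate early genes, 2 rose, 8 fell and 10 did not pass in males, against 0, 5 and 15 in females. Adjusted over this list alone, 11 and 3 passed. That list did not pass camera (camera adjusted p = 0.246 in males and 0.532 in females), and its female median changed sign under TPM. Junb fell in both sexes (-0.66 and -0.47). Fos fell in males (-1.08 ± 0.22, adjusted p = 0.00122), as did the activity-dependent factor Npas4 (-0.93 ± 0.18, adjusted p = 6.6e-04), and Ier2 fell in females (-0.81). Among the 10 sex steroid genes, 2 were higher and 2 lower in stressed males and 6 did not pass, with 3, 3 and 4 in females. Sex steroid calls adjusted over the list alone numbered 4 and 6. Star fell, with the values given for the largest changes, and camera did not pass (camera adjusted p = 0.817 in males and 0.632 in females). The X escape list (9 measured) had 4 rises, 2 falls and 3 not passing in males, and 4, 2 and 3 in females. X escape genes gave 6 and 6 calls adjusted over the list alone, and camera did not pass (camera adjusted p = 0.548 in males and 0.532 in females). Usp9x, a deubiquitinase, rose by 1.69 and 1.68, Kdm6a by 0.28 and 0.33 and Ddx3x by 0.34 and 0.28 on the log2 scale. Xist stood at 1.48 in males (adjusted p = 0.137; 1.86, past the threshold, without stressed male library 1) and 0.73 in females (adjusted p = 0.263). In males Xist was at 2.14 without non-stressed male library 4 and 0.78 without stressed male library 4. Among these genes, calls ended with the length and GC trend removed (Kdm6a in males and Clock, Tef, Junb, Ier2 and Kdm6a in females), after rescaling to TPM (Junb in females) and with array weights (Ier2 in females). Strand doubt applies to Dbp, Tef, Junb and Xist.

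None of the 4 Y-linked genes passed with stress in males, where Ddx3y (-0.16 ± 0.28), Eif2s3y (-0.25 ± 0.28), Kdm5d (0.37 ± 0.26) and Uty (0.19 ± 0.21) had adjusted p of 0.677, 0.498, 0.258 and 0.5004 (0 rose and 0 fell). In females, where their counts were few, Ddx3y (-3.86 ± 0.96, adjusted p = 0.00365) and Eif2s3y (-2.73 ± 0.99, adjusted p = 0.0311) fell, and Kdm5d (-1.65) and Uty (-0.58) did not pass. Y-linked calls adjusted over the list alone numbered 0 in males and 2 in females, and camera did not pass (camera adjusted p = 0.725 in males and 0.473 in females). Both female calls were lost by limma and without non-stressed female libraries 1 and 4, and that of Eif2s3y after rescaling to TPM or with the compared groups alone. Without non-stressed female library 1, Ddx3y was at -2.85 and Eif2s3y, no longer past the threshold, at -1.10. Eif2s3y also missed the threshold without stressed female library 2, 3 or 4 (-2.28, -2.39 and -2.54), and without stressed female library 1 Ddx3y and Eif2s3y were at -4.97 and -4.39. Kdm5d passed without non-stressed female library 2 or 3 or stressed female library 1 (-2.07, -2.07 and -2.96), and without non-stressed female library 1 it was at -0.55. In males Ddx3y turned positive after rescaling to TPM (0.07), and Kdm5d and Uty negative with the length and GC trend removed (-0.03 and -0.09). Without non-stressed female libraries 1 and 4 that group had no Kdm5d or Uty count and gives no fold. Uty was positive without non-stressed female library 1 (0.52, 2 counts) and was at -2.21 without stressed female library 1.

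Markers of hippocampal neurons moved in both directions. Of 10 measured dentate gyrus granule neuron genes, 7 rose, 2 fell and 1 did not pass in males, against 7, 2 and 1 in females. For dentate gyrus granule neuron genes adjusted over the list alone, 9 and 9 passed, and camera did not pass (camera adjusted p = 0.0708 in males and 0.202 in females). In males it did, with a rise, without non-stressed female libraries 1 and 4 (adjusted p = 0.0349) and without non-stressed male library 4 or non-stressed female library 4 or stressed male library 2 (adjusted p from 0.00850 to 0.0369). Dsp rose (1.20 ± 0.14 in males and 0.77 ± 0.14 in females), as did Pdzd2 (1.23 ± 0.17 and 1.06 ± 0.17) and the axon guidance gene Sema5a (0.72 and 0.76), and in males the granule cell transcription factor Prox1 (0.59). The tryptophan-degrading enzyme gene Tdo2 fell in females (-0.83). Among the 7 CA1 neuron genes, 1 was higher and 1 lower in stressed males and 5 did not pass, with 3, 1 and 3 in females. CA1 neuron calls adjusted over the list alone numbered 2 and 4, and Pou3f1 fell (-0.48 and -0.63). The CA2 and CA3 neuron list (10 measured) had 3 rises, 1 fall and 6 not passing in males, and 2, 1 and 7 in females. CA2 and CA3 neuron genes gave 4 and 3 calls adjusted over the list alone, with Map3k15 higher (0.84 and 0.89). Of 13 measured GABAergic interneuron genes, 3 rose, 5 fell and 5 did not pass in males, against 3, 7 and 3 in females. Adjusted over this list alone, 8 and 10 passed. The interneuron transcription factor gene Dlx1 (-1.16 ± 0.13 and -1.16 ± 0.12), the neuropeptide gene Cck (-0.78 ± 0.16 and -1.07 ± 0.16) and the calcium-binding protein gene Pvalb (-0.80 ± 0.22 and -1.06 ± 0.22) fell. Among the 10 adult neurogenesis genes, 1 was higher and 4 lower in stressed males and 5 did not pass, with 1, 5 and 4 in females. Adult neurogenesis calls adjusted over the list alone numbered 5 and 6. The progenitor and early neuron factors Sox4 (-0.58 and -0.65) and Neurod1 (-0.77 and -0.69) fell, and Dcx, a microtubule protein of immature neurons, rose (0.49 and 0.55). None of these lists passed camera in either sex, and the median of the neurogenesis list in males changed sign under TPM. Some of these calls did not last with the length and GC trend removed (Sema5a, Cck, Pvalb and Dcx in males and Sema5a, Neurod1 and Dcx in females), after rescaling to TPM (Pou3f1 in males), with array weights (Map3k15 in females) and without non-stressed female libraries 1 and 4 (Map3k15 in females). Strand doubt applies to Dsp, Pdzd2, Sema5a, Prox1, Pou3f1, Map3k15 and Dlx1, which overlap opposite-strand genes.

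No list of genes that mark regions next to the hippocampus passed camera in either sex. Over all tested genes, 39.7% were called in males and 49.3% in females. For the thalamus, 1 of 9 genes rose and 0 fell in males and 0 and 1 in females, with 0 and 0 calls adjusted over the list alone. For the striatum, 1 of 10 genes rose and 3 fell in males and 1 and 2 in females, with 4 and 3 such calls. For the hypothalamus, 0 of 7 genes rose and 1 fell in males and 0 and 2 in females, with 1 and 2 such calls. For the neocortex, 0 of 9 genes rose and 3 fell in males and 1 and 2 in females, with 3 and 3 such calls. For the cerebellum, 1 of 5 genes rose and 1 fell in males and 1 and 0 in females, with 2 and 1 such calls. The phosphodiesterase gene Pde10a rose (0.74 and 0.83), as did the calcium channel gene Itpr1 (0.69 and 0.68), and the neuropeptide gene Cartpt fell (-1.55 ± 0.34 and -1.35 ± 0.33). Lists for tissue lining the ventricles and the brain surface did not pass camera either. For the choroid plexus, 0 of 16 genes rose and 0 fell in males and 0 and 0 in females, with 0 and 0 calls adjusted over the list alone. For meningeal fibroblasts, 1 of 11 genes rose and 0 fell in males and 0 and 2 in females, with 0 and 2 such calls. For ependymal cells, 0 of 8 genes rose and 4 fell in males and 0 and 4 in females, with 4 and 4 such calls. For blood, 1 of 5 genes rose and 0 fell in males and 0 and 1 in females, with 1 and 0 such calls. Mia fell (-1.45 ± 0.32 and -1.51 ± 0.31) and the prostaglandin synthase gene Ptgds fell in females (-0.75). The haemoglobin gene Hba-a2 rose in males (2.68 ± 0.49, or 2.03 without stressed male library 2). Calls in this group were lost with the length and GC trend removed (Itpr1 in males and Itpr1 and Ptgds in females), after rescaling to TPM (Ptgds in females), after quantile normalization (Ptgds in females), with array weights (Ptgds in females) and without non-stressed female libraries 1 and 4 (Ptgds in females). Strand doubt applies to Pde10a and Itpr1.

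Glial and vascular markers changed in part. Of 18 measured myelin and oligodendrocyte genes, 0 rose, 6 fell and 12 did not pass in males, against 0, 5 and 13 in females. Adjusted over this list alone, 3 and 4 passed. Opalin, a myelin protein gene, fell (-0.74 ± 0.12 and -0.65 ± 0.12), as did the lineage factor Olig1 (-0.35 and -0.50), and the list's median changed sign under TPM in both sexes. The oligodendrocyte precursor list (9 measured) had 3 rises, 1 fall and 5 not passing in males, and 2, 1 and 6 in females. Oligodendrocyte precursor genes gave 4 and 3 calls adjusted over the list alone. The growth factor receptor gene Pdgfra rose (0.58 ± 0.07 and 0.49 ± 0.07) and C1ql1 fell (-0.50 and -0.57). Among the 12 astrocyte genes, 3 were higher and 4 lower in stressed males and 5 did not pass, with 4, 4 and 4 in females. Astrocyte calls adjusted over the list alone numbered 7 and 8. Sox9 fell (-0.48 ± 0.07 and -0.52 ± 0.07), the connexin gene Gjb6 fell in females (-0.65) and the receptor gene Fgfr3 rose in males (0.32). The microglia list (14 measured) had 0 rises, 6 falls and 8 not passing in males, and 1, 4 and 9 in females. Microglia genes gave 7 and 5 calls adjusted over the list alone. Aif1, which codes for Iba1, fell (-0.59 and -0.72), Tmem119 fell in males (-0.34) and the receptor gene Csf1r rose in females (0.41). Of 12 measured endothelial genes, 2 rose, 3 fell and 7 did not pass in males, against 1, 4 and 7 in females. For endothelial genes adjusted over the list alone, 5 and 4 passed. The tight junction gene Cldn5 (-0.77 and -0.99) and Ly6c1 (-0.67 and -0.68) fell. Among the 8 mural cell genes, 3 were higher and 0 lower in stressed males and 5 did not pass, with 3, 3 and 2 in females. Mural cell calls adjusted over the list alone numbered 3 and 7. The potassium channel subunit gene Abcc9 rose (0.57 and 0.55), Tagln rose in males (1.44) and Vtn fell in females (-0.54). None of these lists passed camera. Glial and vascular calls ended with the length and GC trend removed (Olig1, C1ql1, Fgfr3, Aif1, Tmem119, Cldn5, Ly6c1 and Abcc9 in males and Olig1, Pdgfra, C1ql1, Aif1, Ly6c1, Abcc9 and Vtn in females), after rescaling to TPM (Olig1, C1ql1 and Tmem119 in males), with array weights (Abcc9 in females) and without non-stressed female libraries 1 and 4 (Aif1 in females). Opposite-strand overlap makes Olig1, Pdgfra, Fgfr3, Csf1r, Abcc9 and Tagln uncertain.

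Glutamate receptor genes that changed rose in both sexes, and lists of other receptors and of synapse genes were mixed. Of 22 measured glutamate receptor genes, 8 rose, 0 fell and 14 did not pass in males, against 9, 0 and 13 in females. For glutamate receptor genes adjusted over the list alone, 7 and 7 passed. The list passed camera in females (camera adjusted p = 0.0975 in males and 0.0252 in females), with adjusted p = 0.888 and 0.897 with an estimated correlation. It did not pass with the length and GC trend removed, with no opposite-strand neighbour, without non-stressed female libraries 1 and 4 or without non-stressed female library 1 (adjusted p = 0.0532), and its interaction test did not pass (camera adjusted p = 0.143). The NMDA receptor subunit genes Grin2b (1.01 ± 0.17 and 1.07 ± 0.17) and Grin1 (0.52 ± 0.13 and 0.71 ± 0.13) and the kainate receptor gene Grik3 (0.83 ± 0.22 and 0.96 ± 0.22) rose. The GABA receptor list (14 measured) had 4 rises, 2 falls and 8 not passing in males, and 5, 2 and 7 in females. GABA receptor genes gave 6 and 8 calls adjusted over the list alone, with rises at Gabrb1 (0.52 and 0.62), Gabrg3 (0.63 and 0.41) and Gabrb2 (2.06 and 2.05). Without non-stressed female library 3, the female values of Gabrb2 and Adra1a became 3.12 and 1.97. Among the 23 monoamine genes, 3 were higher and 3 lower in stressed males and 17 did not pass, with 4, 4 and 15 in females. Monoamine calls adjusted over the list alone numbered 6 and 8. The dopamine receptor gene Drd5 (0.73 and 0.84) and the adrenoceptor gene Adra1a (1.54 and 1.34) rose and Adrb1 fell (-0.57 and -0.52). Of 27 measured synaptic genes, 5 rose, 2 fell and 20 did not pass in males, against 6, 2 and 19 in females. For synaptic genes adjusted over the list alone, 6 and 7 passed. The active zone scaffold genes Pclo (0.74 and 0.76) and Bsn (0.90 and 0.95) rose. The neurotrophic factor list (12 measured) had 3 rises, 5 falls and 4 not passing in males, and 2, 5 and 5 in females. Neurotrophic factor genes gave 8 and 7 calls adjusted over the list alone. The secreted peptide genes Vgf (-0.56 ± 0.08 and -0.59 ± 0.08) and Cort (-0.75 ± 0.17 and -0.95 ± 0.17) fell. Of these lists, no other passed camera. Bdnf had a log2 fold change of -0.33 ± 0.13 in males (adjusted p = 0.0445). That call was lost when non-stressed male library 1 or 4, non-stressed female library 1 or 3 or any stressed library was left out (values from -0.37 to -0.24). In females it stood at -0.24 ± 0.13 (adjusted p = 0.128; -0.32, past the threshold, without non-stressed female library 2, and 0.03 after rescaling to TPM). Receptor and peptide calls were lost with the length and GC trend removed (Gabrb1 and Cort in males and Gabrg3 in females), after rescaling to TPM (Bdnf in males and Adrb1 in females), with pool size weights (Bdnf in males), with no filter (Bdnf in males), with median-ratio scaling (Bdnf in males), by DESeq2 (Bdnf in males) and with thinned counts (Bdnf in males). Strand doubt applies to Grin2b, Grin1, Gabrb1, Gabrg3, Drd5, Pclo, Bsn and Bdnf. Rises here went with the higher share of counts at genes over 6 kb in stressed libraries given above.

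Most genes for ribosomal proteins and most nuclear genes of the respiratory chain fell in both sexes. Of 75 measured cytosolic ribosomal protein genes, 2 rose, 58 fell and 15 did not pass in males, against 1, 68 and 6 in females. For cytosolic ribosomal protein genes adjusted over the list alone, 64 and 71 passed. Their median log2 fold change was -0.70 in males and -0.93 in females (camera adjusted p = 3.6e-16 in males and 2.0e-20 in females; adjusted p = 0.888 and 0.897 with an estimated correlation). Under TPM it was -0.46 and -0.57. Rpl13a (-1.91 ± 0.11 and -2.07 ± 0.12), Rpl23a (-2.07 ± 0.14 and -2.24 ± 0.14), Rpl11 (-1.71 and -1.91) and Rps7 (-1.29 and -1.30) were among those that fell. The nuclear oxidative phosphorylation list (67 measured) had 0 rises, 53 falls and 14 not passing in males, and 1, 60 and 6 in females. Nuclear oxidative phosphorylation genes gave 54 and 61 calls adjusted over the list alone. Its median was -0.53 in males and -0.84 in females (camera adjusted p = 1.7e-07 in males and 3.4e-12 in females; adjusted p = 0.888 and 0.897 with an estimated correlation), with Ndufs5 (-1.40 ± 0.17 and -1.56 ± 0.17), Cox7c (-1.14 and -1.19) and Cox5b (-0.99 and -1.15). Under TPM this median was -0.30 and -0.51. The median exonic length was 1830 bases for the ribosomal and 1828 for the respiratory list. With the length and GC trend removed, the ribosomal list still passed (medians -0.37 and -0.60), and the respiratory list passed in females and not in males (medians -0.44 and -0.15). Stressed libraries held a lower share of counts at genes under 1 kb and mitochondrially encoded genes, as given above. Among the 13 mitochondrially encoded genes, 4 were higher and 5 lower in stressed males and 4 did not pass, with 4, 3 and 6 in females. Mitochondrially encoded calls adjusted over the list alone numbered 11 and 7. The gene mt-Nd6 fell (-4.09 ± 0.21 and -4.35 ± 0.21), and the ATP synthase subunit genes mt-Atp8 (2.83 ± 0.24 and 3.37 ± 0.25) and mt-Atp6 (1.16 ± 0.11 and 1.32 ± 0.11), which overlap each other, rose. The list did not pass camera (adjusted p = 0.813 in males and 0.317 in females). With the length and GC trend removed it did at the preset correlation, rising in both sexes (medians 0.43 and 0.53, adjusted p = 4.4e-04 and 6.8e-07). Overlap with opposite-strand genes leaves Rpl23a and mt-Nd6 uncertain.

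**Figure D5:**
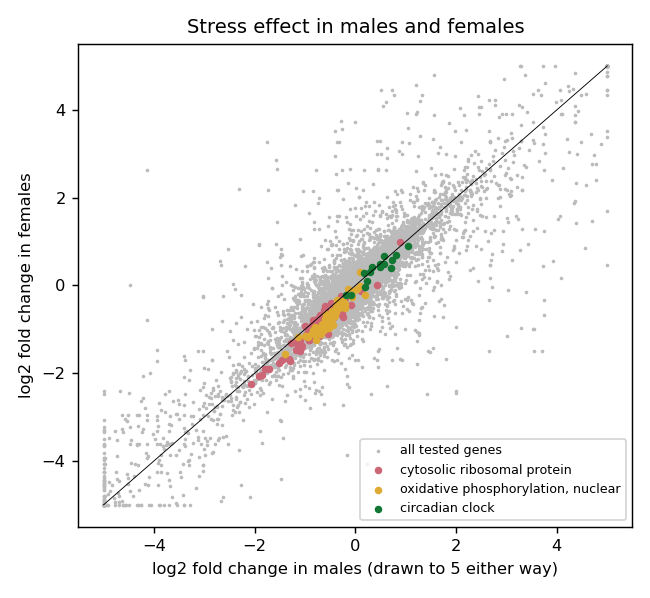
Log2 fold change with stress in males (horizontal) and females (vertical), 1 point per tested gene, drawn to 5 either way, with the line of equal change. Ribosomal protein genes (median -0.70 and -0.93) lie mostly below 0 in both sexes and clock genes (median 0.49 and 0.41) mostly above.

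Genes of protein folding fell where they changed. Of 19 measured endoplasmic reticulum stress genes, 0 rose, 8 fell and 11 did not pass in males, against 0, 12 and 7 in females. Adjusted over this list alone, 8 and 13 passed. The list passed camera in females (camera adjusted p = 0.270 in males and 0.0364 in females), with adjusted p = 0.888 and 0.897 with an estimated correlation. It did not pass with the length and GC trend removed, with no opposite-strand neighbour, without non-stressed female libraries 1 and 4 or without non-stressed female library 1 or 4 or stressed female library 1 (adjusted p from 0.0580 to 0.0723). The chaperone gene Calr (-0.54 ± 0.08 and -0.61 ± 0.08) and the secreted factor gene Manf (-0.69 ± 0.14 and -1.05 ± 0.14) fell. Among the 14 heat shock and cold-inducible genes, 0 were higher and 4 lower in stressed males and 10 did not pass, with 0, 9 and 5 in females. Calls adjusted over that list alone numbered 4 and 9. The mitochondrial chaperonin gene Hspe1 (-1.22 and -1.56), Cryab (-0.66 and -0.82) and the cold-induced RNA-binding protein gene Cirbp (-0.46 and -0.34) fell. The inflammatory list (11 measured) had 0 rises, 1 fall and 10 not passing in males, and 3, 1 and 7 in females. Inflammatory genes gave 1 and 3 calls adjusted over the list alone. Of 17 measured interferon and antigen presentation genes, 0 rose, 2 fell and 15 did not pass in males, against 0, 9 and 8 in females. Adjusted over this list alone, 1 and 9 passed. B2m, the light chain of class I molecules, fell (-0.69 ± 0.15 and -0.74 ± 0.15), and Ifitm3 fell in females (-0.70). Among the 9 histone genes, 0 were higher and 4 lower in stressed males and 5 did not pass, with 0, 5 and 4 in females. Histone calls adjusted over the list alone numbered 4 and 5. The linker histone genes H1f0 (-0.63 ± 0.06 and -0.70 ± 0.06) and H1f2 (-0.74 and -1.04) fell. The nuclear-retained long noncoding RNA list (7 measured) had 2 rises, 1 fall and 4 not passing in males, and 3, 0 and 4 in females. That list gave 3 and 3 calls adjusted over it alone. Snhg11 fell in males (-0.23). Apart from the endoplasmic reticulum list in females, none of these passed camera. In females the list of histone genes passed, with a fall, without non-stressed male library 2 or 4 or non-stressed female library 2 or stressed female library 3 (adjusted p from 0.0330 to 0.0497) and that of heat shock genes without non-stressed female library 2 (adjusted p = 0.0482). The median, mean and camera direction of a list differed in sign in males for sex steroid, endothelial, thalamus, cerebellum, monoamine and inflammatory genes and in females for corticoid, cerebellum, GABA receptor and monoamine genes, none of which passed. Chaperone, immune and histone calls ended with the length and GC trend removed (Cryab, B2m and H1f2 in males and Cirbp, B2m and Ifitm3 in females), after rescaling to TPM (Snhg11 in males and Cirbp in females), after quantile normalization (Snhg11 in males and Cirbp in females) and with no filter (Snhg11 in males). Strand doubt applies to Manf, Hspe1, Cryab, B2m and H1f0.

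The stress effects in males and females (separate libraries) overlapped, which library differences between conditions could also give. Of genes that rose, 2790 did so in both sexes, where 718 would by chance (product of both counts over all tested genes), and of genes that fell 3238, against 1015. By edgeR 0 genes were called in opposite directions. Across the 17569 genes, not independent replicates, log2 fold changes correlated with Pearson's r = 0.929, and across the 5927 with no opposite-strand neighbour with r = 0.834.

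By edgeR and DESeq2, no gene was called as changing with stress by a different amount in the sexes. The edgeR interaction test called 0 of 17569 genes, with 374 at an unadjusted p under 0.05. DESeq2 called 0 and limma 0, or 1 with a pseudocount of 0.1 and 1 after rescaling to TPM. On simulated counts, drawn with the same spread in all groups, the same test found 54 of 100 interactions of 2-fold and 7 of 100 of 1.5-fold. The 10 genes with the smallest p, none passing (lowest adjusted p = 1.000), were the matrix protein gene Mgp (female minus male stress effect -0.99 ± 0.25), Smim3 (-0.71 ± 0.18), the caveolar coat gene Cavin1 (-0.60 ± 0.16) and Uaca (-0.59). The rest were Ddx3y (-3.70 ± 1.02), Nudt6 (0.90), the transcription factor gene Maf (-0.47), Mrps35 (-0.45), Hba-a1 (-1.98 ± 0.60) and Catsperd (-0.79). Nor did Xist (-0.75 ± 0.94), Eif2s3y (-2.47), Kdm5d (-2.02), Uty (-0.77), Nr3c1 (-0.08 ± 0.10), Nr3c2 (0.11 ± 0.13), Fkbp5 (-0.34 ± 0.14) or Bdnf (0.10 ± 0.18) pass. The Y-linked genes had few female counts, and without non-stressed female library 1 values were -2.69 for Ddx3y, -0.84 for Eif2s3y, -0.92 for Kdm5d and 0.33 for Uty (2 counts left). Without stressed female library 1 they were -4.82, -4.13, -3.33 and -2.40. Xist was at -1.40 without non-stressed and -0.04 without stressed male library 4, and Hba-a1 at -1.31 without stressed male library 2. Without non-stressed female libraries 1 and 4 signs changed for Eif2s3y (0.15) and Nr3c2 (-0.02), and Kdm5d and Uty had no count in that group. The limma fits turned Xist positive (0.22 to 0.54), and so was Eif2s3y at a pseudocount of 1 (0.06) and with array weights (0.05). Strand doubt applies here to Uaca, Nudt6, Maf, Xist, Nr3c2, Fkbp5 and Bdnf.

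Among the gene lists, 9 of 41 passed camera for the interaction at the preset correlation and 0 with an estimated one. The stress effect was lower in females than in males, by the median, for nuclear oxidative phosphorylation genes (median difference -0.24, camera adjusted p = 2.9e-07; Sdhc at -0.28) and ribosomal protein genes (-0.23, 3.1e-05; Rps16 at -0.41). These had adjusted p = 0.694 and 0.772 with an estimated correlation, and the direction of both tests turned positive without non-stressed female libraries 1 and 4. It was also lower for Y-linked genes (camera adjusted p = 9.0e-06), blood (7.6e-09), meningeal fibroblast (7.0e-05; Ptgds at -0.77), interferon and antigen presentation (0.0102; Cd74 at -1.10) and endoplasmic reticulum stress genes (0.0102; Sdf2l1 at -0.49), with adjusted p = 0.462, 0.417, 0.544, 0.620 and 0.544 with an estimated correlation. It was positive for mitochondrially encoded (camera adjusted p = 8.9e-04, mt-Cytb at 0.31) and inflammatory genes (0.0125, C3 at 1.65), with adjusted p = 0.544 and 0.544 with an estimated correlation. Without non-stressed female libraries 1 and 4 the Y-linked, interferon and endoplasmic reticulum lists did not pass. With no opposite-strand neighbour the interferon and endoplasmic reticulum lists did not pass, and the mitochondrially encoded list could not be tested. With 1 library left out at a time, a setting for lists chosen after seeing the data, the Y-linked and blood lists passed in all 16 fits. Those of oxidative phosphorylation and ribosomal protein genes were lost without non-stressed female library 4 (adjusted p = 0.889 and 0.0835), where the direction of both turned positive. Inflammatory genes did not pass without non-stressed male library 1 or non-stressed female library 3 or stressed female library 3 (adjusted p from 0.0756 to 0.196), and C3 moved to 0.30 without stressed female library 3. Mitochondrially encoded genes did not pass without non-stressed female library 3 or stressed female library 1 (adjusted p from 0.0614 to 0.172), nor meningeal genes without non-stressed female library 3 (adjusted p = 0.0547). Interferon and antigen presentation genes were lost without non-stressed male library 1 or 4 or non-stressed female library 4 or stressed male library 2 or stressed female library 4 (adjusted p from 0.0660 to 0.369) and endoplasmic reticulum genes without non-stressed male library 1 or 4 or non-stressed female library 1 or 4 or stressed female library 1 (adjusted p from 0.0503 to 0.0835).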

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

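The tests of trend, thinning and opposite-strand neighbours below, and the counting test for the Y-linked genes, were chosen after seeing the data. In 31 of 513 groups of 4 values reported above, 1 library lay far from the other 3 relative to the range (6.04%; chance alone does this in about 1 in 20). Values are CPM unless given as a share. In chronic-stressed female library 2 these were the ribosomal protein share at 0.641% and Il4 at 0.0382. Chronic-stressed male library 2 stood apart with the haemoglobin share at 0.0324%, Cd74 at 10.1, H1f2 at 20.99, Hba-a1 at 89.3, Hba-a2 at 34.97 and Ptgds at 978. C1qa at 54.8, C3 at 19.97 and Nudt6 at 3.45 stood apart in chronic-stressed female library 3. In non-stressed female library 4 these were C1ql1 at 9.73, Mrps35 at 27.8, Pomc at 9.79 and Prl at 186. Chronic-stressed female library 1 stood apart with Eif2s3y at 0.387, Uty at 0.221 and Vgf at 98.7. Gabrg3 at 15.5 stood apart in non-stressed male library 2. In chronic-stressed female library 4 these were Gnpnat1 at 11.5, Hba-a1 at 21.5 and Prl at 0.629. Non-stressed male library 1 stood apart with Grm7 at 42.2, Kdm5d at 35.5 and Ndufb10 at 122. Itpr1 at 369.9 and Xist at 660.2 stood apart in non-stressed female library 3. In chronic-stressed male library 1 these were Ly6c1 at 11.2, Proz at 0.0536 and Uty at 20.4. Chronic-stressed male library 3 stood apart with Pclo at 354.

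The male and female stress effects differed by the camera test of the interaction for 9 gene lists: Y-linked genes (adjusted p = 9.0e-06), meningeal fibroblast (adjusted p = 7.0e-05), blood (adjusted p = 7.6e-09), oxidative phosphorylation (adjusted p = 2.9e-07), mitochondrially encoded (adjusted p = 8.9e-04), cytosolic ribosomal protein (adjusted p = 3.1e-05), inflammatory (adjusted p = 0.0125), interferon-induced and antigen presentation (adjusted p = 0.0102) and endoplasmic reticulum stress (adjusted p = 0.0102). With 1 library left out at a time, a setting for lists chosen after seeing the data, each list but the Y-linked and blood ones was lost in at least 1 fit. None held with an estimated correlation, and no single gene passed (edgeR, 374 at an unadjusted p under 0.05; DESeq2 0).

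Stressed and non-stressed libraries differed at many genes in both sexes (6976 in males and 8668 in females), and the conditions also differed in the make-up of the libraries. The tables argue against depth as the cause, since thinning all libraries to the lowest total changed the number of calls by 1.07 times at most, and against a trend with gene length and GC content as the whole cause, since at least 56.1% of the same genes stayed called once it was removed. Strand kept apart in the counts of one condition and not of the other may account for part: genes with over 50% of their exonic bases shared with opposite-strand exons had a median log2 fold change 0.55 above genes sharing none in males and 0.63 in females, and 79.0% of the genes over 4-fold in both sexes had an opposite-strand neighbour, against 66.3% of all, just under the 80% set for that test. It cannot be the whole cause, since at least 35.6% of genes without such a neighbour were called. An effect of chronic stress stays open and cannot be told apart from other differences between the library sets, which follow the condition in every library; the list of glucocorticoid-responsive genes did not pass (camera adjusted p = 0.523 in males and 0.742 in females).

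Y-linked counts in non-stressed female libraries 1 and 4 came to 3.36% and 1.25% of the male level over Ddx3y, Eif2s3y, Kdm5d and Uty (100 and 41 counts), against 0.173% and 0.106% in libraries 2 and 3. RNA or reads of male mice in the library would put the 4 genes at one share. In library 1 the highest share was 2.52 times the lowest, between the bounds of 2 and 4 set for the test, and Uty, the lowest, had 4 counts. A counting test of one common share gave p = 0.237 in library 1 and 0.0389 in library 4 (chi-square test with p from simulated counts). Few counts keep this open, and no biological explanation was tested.

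Prolactin in non-stressed female library 4 stood at 186 CPM, against at most 2.20 in the other 15 libraries. For pituitary tissue in the library the test asked for 3 of 5 further pituitary hormone genes over 10 times the median of the other libraries, and 3 were, namely Gh (73.2 CPM against at most 1.07), Pomc (9.79 against at most 2.09) and Cga (1.99 against at most 0.516). The bar was met, but only with Cga, where that median is 0 and any count passes, so the explanation stays open. Pomc is also a hypothalamus marker. Lhb had no count in that library and Tshb stood at 0.854 CPM, below the highest of the others (1.73). A difference between mice in the expression of these genes was not tested.

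Other splits of the same libraries were run with limma, fitted to the 8 libraries of the groups compared and, for the interaction, to all 16. For the comparisons of groups, the counts of real calls here therefore differ from those of limma fitted to all 16. For the sexes in non-stressed mice, 7 genes were called and at most 4 in the other splits, and in stressed mice 10 against at most 4. For stress in males 8456 against at most 0, and in females 6188 against at most 2. In each, only the real split of 35 gave as many, the lowest share possible (1 of 35), too coarse to exclude chance. For the interaction the real division gave 0 calls, a count that each of the 100 splits reaches by construction, so these splits test nothing about it. The highest of the others gave 454. A split that calls so many points to some structure of the samples, and which one was not tested.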

How the results depend on the processing

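The settings without TMM, with the length and GC trend removed, with no opposite-strand neighbour, without non-stressed female libraries 1 and 4 and with thinned counts were chosen after seeing the data. Of 9001 values for 261 named results, 8825 kept their side of the threshold, 138 were no longer past it, 37 newly were and 1 call changed sign: Nr3c1 in males, -0.019 with the trend removed. Some calls resting on 1 library were not named, which favours stability. Of those that kept their side, 42 values of 19 results changed sign, past the threshold in neither fit. Removing the trend ended 44 calls, the most. Genes called in non-stressed mice between the sexes were 15 by DESeq2 and 16 without libraries 1 and 4. In stressed mice they were 11 by DESeq2, 13 with array weights and 11 with the compared groups alone. With no opposite-strand neighbour, calls were 2110 in males and 2650 in females, and with the trend removed as well 1699 and 2120, where fewer genes were tested; without libraries 1 and 4 the female count was 5594, where fewer libraries were fitted. Limma called 1 interaction at a pseudocount of 0.1 and 1 under TPM. Leaving out each library in turn, compared or not, gave 8 to 11 and 7 to 9 for the sexes in non-stressed and stressed mice, 5847 to 8583 and 7135 to 9829 for stress in males and females, and 0 for the interaction. The replicate block gave 9, 7, 6929, 8592 and 0, though replicate numbers do not pair the libraries (same-number correlations from -0.23 to 0.17).

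Lists passing, in the order sexes in non-stressed and stressed mice, stress in males and females, and interaction, were 2, 3, 0, 0 and 0 with an estimated correlation, and 2, 2, 19, 16 and 0 by fry, which asks another question. With no opposite-strand neighbour they were 6, 5, 2, 2 and 6, where lists with under 3 such genes could not be tested, and without libraries 1 and 4 3 for stress in females and 9 for the sexes in non-stressed mice. Without those libraries the ribosomal protein and oxidative phosphorylation lists changed direction in the sex comparison of non-stressed mice (adjusted p = 1.1e-18 and 1.1e-15) and in the interaction (adjusted p = 3.6e-22 and 2.8e-15). List tests with each library left out in turn, chosen after seeing the data, gave 8 to 14 lists for the sexes in non-stressed mice (8 without non-stressed male library 1 and 8 without non-stressed female library 4), 7 to 11 in stressed mice, 3 to 4 and 3 to 7 for stress in males and females (3 in females without non-stressed female library 1) and 6 to 13 for the interaction. Some fits also brought in lists that did not pass with all libraries: clock, glucocorticoid-responsive and synaptic genes between the sexes of non-stressed mice, ribosomal protein, interferon, mitochondrial and myelin genes in stressed mice, and choroid plexus, clock, dentate granule neuron, endothelial, glutamate receptor, heat shock, hypothalamus, immediate early, microglia, mural and thalamus genes for the interaction. Clock genes also passed between the sexes of non-stressed mice and for the interaction with the trend removed (adjusted p = 0.0235 and 0.0141). Without non-stressed female libraries 1 and 4, lists that newly passed were those of clock and microglia genes between the sexes of non-stressed mice, ribosomal protein genes in stressed mice, and microglia, mural, dentate granule neuron and clock genes for the interaction. The cause was not tested for these changes, apart from those that come from testing fewer genes or libraries. At the depth of these libraries, simulated changes of 1.5-fold were found in 37 to 56 of 100 cases in the 4 comparisons of groups.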

Other observations

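The tests by exon share here were chosen after seeing the data. Calls with stress were more frequent among genes with many exonic bases opposite to exons of another gene. Among 12198 genes with no such overlap, 38.1% were called in males and 47.9% in females, against 69.0% and 73.6% of the 277 genes with over 0.5. In the last group 124 genes rose and 67 fell in males and 135 and 69 in females. In the mitochondrial genome mt-Nd6, encoded on the other strand than its neighbours, stood at 0.0587 times its non-stressed level in stressed males and 0.0489 times in stressed females.

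Spread within groups was larger in non-stressed females than in the other groups: the ribosomal protein share ran from 0.866% to 1.80% there, and from 0.992% to 1.11% in non-stressed males. Xist counts were not 0 in males, from 0.0536 to 11.5 CPM in the stressed group, where stressed females stood at 937 ± 67.7 CPM.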
